A study of Homo sapiens with 6 samples.

How the data were processed

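Poly(A) RNA of OVCAR-5 cells over-expressing GFP or FTO-GFP was extracted with Trizol, isolated with Dynabeads and made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. The deposited values are raw counts of reads per gene name, 1 table per library, which the authors made with HTSeq after trimming with Trim Galore 0.4.4 and cutadapt 1.14 and aligning with STAR 2.5.2 to GRCh38, per the submitters' processing notes. The HTSeq version, its strand setting and the annotation release are not given in the sources used here. The notes also name edgeR.

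Each library was assigned to its group and replicate number from its title. The 6 tables shared 56655 gene names, of which 55370 were found in GENCODE 29, the source of positions and gene types (GRCh38), and 1285 were not. Of the names, 106 names matched several loci. Totals ran from 14717297 to 19193962 counts. Counts were simulated for FTO-GFP against GFP from the real means, library sizes and dispersions, with 200 of 16328 genes changed. Of the smallest changes simulated (0.32 on the log2 scale) 38.0% were recovered, with 72.0% of 1.5-fold, 90.0% of 2-fold and all of 4-fold. Of the calls, 9.09% were wrong. Depth and the number of libraries were not varied. Far more genes (5414) were called in the data than were changed here, so recovery there may differ. With no gene changed, 0 were called.

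The main comparison used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and glmQLFit with robust=TRUE and glmQLFTest were fitted with group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors ran from 0.959 to 1.03. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, and their SDs are over 3 libraries.

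The genes named in the text follow a rule set before the data were examined: FTO, PDE1C and PDE4B; the 12 largest rises and 12 largest falls with adjusted p under 0.05, a mean of at least 50 counts and groups that do not overlap, without clone names and pseudogenes; the 4 further genes per direction with the smallest adjusted p; and up to 4 members per list with the smallest adjusted p, plus members that go against their list. Lists on quality and cell identity give abundant members. Some genes that the rule takes are not reported here. The genes named for FTO-GFP replicate 2 in the closing section, ATF3, NR4A2, FOSB, PPP1R15A and DDIT4, were chosen after their values were seen.

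The 30 gene lists were also fixed beforehand. Listed names were matched through older symbols, and 1 name had no match. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 30 lists, each with at least 5 tested members. Camera with an estimated correlation and fry were run as alternatives. Rises and falls within a list were counted over all tested genes and again adjusted over the list alone.

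Replicate pairs were compared by chi-square over genes with at least 20 counts in the pair. Alternatives planned beforehand were RLE, upper-quartile and library-size scaling, FTO left out of the table, no filter and a filter of at least 1 CPM in at least 3 libraries, genes with a mean of at least 50 counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust=FALSE, the replicate number as a block, and each library left out in turn.

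Positional shifts were examined after the main result was seen. Genes placed at a single locus (16023) were ordered along chromosomes 1 to 22 and X, and medians of runs of 50 genes were compared with 100 random orders. Arms, divided at the largest gap between annotated genes, were compared with 10000 random draws of genes and adjusted over 41 arms. In fold changes shuffled over these genes, 100% of a simulated block of 150 genes shifted by 0.5 was found, with 0.239% of other genes called. The simulated shift was larger than any stretch median found in the data (at most 0.44 in size). Recovery of smaller or shorter shifts was not examined. GC content and length were taken from each gene's longest transcript and were known for 98.5% of tested genes; their trends were fitted per library with splines. DRACH motifs (the sequence context of m6A) were counted in the longest annotated 3' UTR of protein-coding genes with at least 100 bases. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for these steps.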

Results

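RNA was sequenced from OVCAR-5 cells, an established human ovarian cancer line, that over-expressed either green fluorescent protein alone (GFP, the control) or FTO joined to it (FTO-GFP). The series names the line, while the sample labels give ascites as the source and high grade serous as the tumour type. FTO removes methyl groups from N6-methyladenosine (m6A), the most abundant internal modification of mRNA. The series held 3 GFP and 3 FTO-GFP libraries, which the labels describe as biological replicates. The files gave 1 count per gene name and library, with totals from 14717297 (FTO-GFP replicate 2) to 19193962 (GFP replicate 3) and between 26341 and 27230 genes with a count. Every pair of replicates differed by more than sampling noise, and each library was counted as 1 sample. GFP replicates 1 and 2 differed least, with a chi-square per degree of freedom of 1.21. A difference beyond sampling noise does not by itself show that replicates are independent. The labels do not say whether the replicates of a group came from separately made cell populations, so the p-values measure the spread between these libraries.

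The comparison asks how the transcriptome of these cells differs when FTO is over-expressed. The FTO-GFP cells carried more FTO mRNA, much less CD70, SLC22A17, KCNH2 and RET mRNA, and much more MMP3, ALPP and ITGB4 mRNA. Genes of epithelial cells and targets of YAP and TEAD were higher as groups, and genes of hypoxia, glycolysis and DNA replication were lower, by camera with a preset correlation. With an estimated correlation the epithelial list passed (adjusted p = 0.0314) and the YAP and TEAD (adjusted p = 0.0706), hypoxia and glycolysis (0.250) and DNA replication (0.416) lists did not. Of 16328 genes tested, 5414 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2701 of them higher and 2713 lower in FTO-GFP. Most of these changes were small, with a median absolute log2 fold change of 0.44 among changed genes. A change of at least 2-fold was found for 939 genes, 347 higher and 592 lower, and 105 genes changed at least 4-fold. All FTO-GFP libraries lay above or below all GFP libraries for 46.7% of tested genes, where chance gives 10%. Scaled by library size alone, 36.9% of the changed genes were higher, against 49.9% with TMM scaling. Among genes with a mean of at least 50 counts, 450 changed at least 2-fold.

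FTO itself (chromosome 16, 53701692 to 54158512, GRCh38) was at 38.2, 37.0 and 36.3 CPM (counts scaled to library size with TMM factors) in the GFP libraries, a mean of 37.2 ± 0.932 (SD, n = 3). In FTO-GFP replicates 1, 2 and 3 it was at 84.3, 144 and 97.0 CPM, a mean of 108 ± 31.3 (SD, n = 3). The log2 fold change was 1.54 ± 0.22 (SE), a 2.91-fold rise (adjusted p = 0.00498), and every FTO-GFP library lay above every GFP library. The counts do not separate the introduced FTO from the endogenous gene. An antisense gene, AC007347.2, overlaps FTO, and the sources used here do not say whether counting used strand.

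PDE1C and PDE4B encode phosphodiesterases, enzymes that break down cyclic nucleotides, and both fell. PDE1C (chromosome 7, 31751179 to 32299329) went from 84.2 ± 2.80 CPM in GFP to 30.6 ± 1.55 CPM in FTO-GFP (SD, n = 3 each), a log2 fold change of -1.46 ± 0.06 (SE, adjusted p = 6.7e-09). PDE4B (chromosome 1, 65792514 to 66374579) went from 149 ± 5.43 to 66.9 ± 21.8 CPM, a log2 fold change of -1.16 ± 0.24 (SE, adjusted p = 0.0191). The FTO-GFP libraries did not carry PDE4B at 1 level: replicates 1 and 3 were at 52.6 and 56.0 CPM and replicate 2 at 92.0 CPM. The PDE4B call missed the threshold with no low-count filter (adjusted p = 0.0562), without GFP replicate 1 (0.0503), without GFP replicate 2 (0.0591) and without FTO-GFP replicate 3 (0.0647). Without FTO-GFP replicate 2 its log2 fold change was -1.46 (adjusted p = 5.94e-30).

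**Figure D1:**
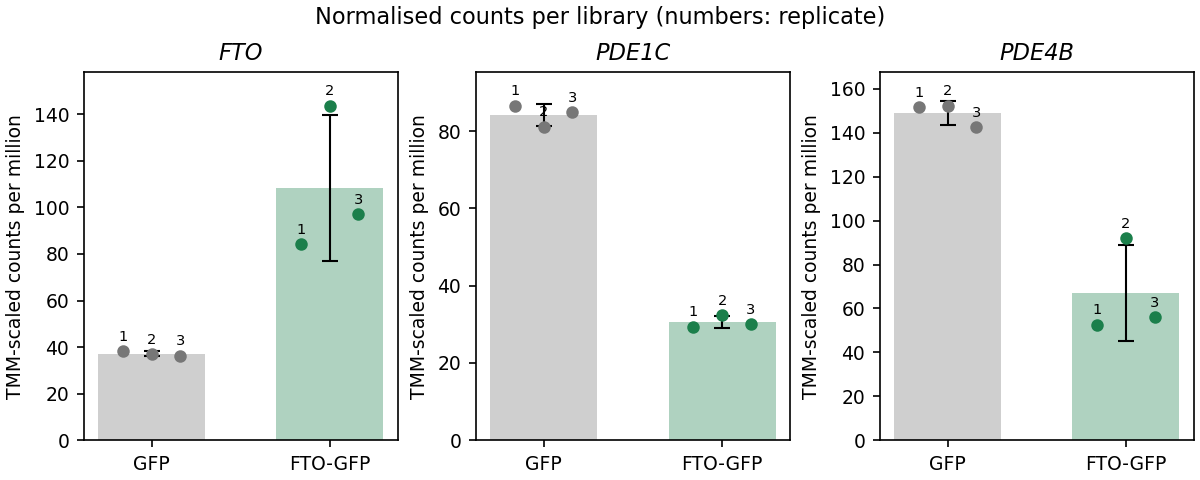
TMM-scaled CPM of FTO, PDE1C and PDE4B in each library, with replicate numbers beside the points; bars are group means and error bars are SDs of 3 libraries. FTO was higher, and PDE1C and PDE4B lower, in every FTO-GFP library than in any GFP library, and FTO-GFP replicate 2 stood at 144 CPM for FTO and 92.0 CPM for PDE4B.

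The phosphodiesterase family as a whole did not move in a single direction. Of its 15 tested members, 5 fell, 3 rose and 7 did not pass, the same counts when adjusted over the list alone. PDE9A fell by 0.86 ± 0.06 and PDE11A fell by 1.40 ± 0.12 on the log2 scale (SE), whereas PDE4D rose by 1.24 ± 0.13, PDE8A by 0.46 ± 0.08 and PDE5A by 0.71 ± 0.19. PDE5A missed the threshold without GFP replicate 3 (adjusted p = 0.0683) and without FTO-GFP replicate 1 (0.0648). The list was lower relative to other genes (camera with a preset correlation of 0.01, adjusted p = 0.00785), with adjusted p = 0.141 with an estimated correlation. The call also ended without the genes of shifted chromosome stretches (adjusted p = 0.0557), 1 of which holds PDE9A. The list holds PDE1C and PDE4B, which the study is known to follow, so its direction is not independent evidence. Among adenylyl cyclases and subunits or anchors of protein kinase A, 5 fell, 3 rose and 11 did not pass, and the list did not pass by camera (adjusted p = 0.468; the same counts adjusted over the list alone), though it did as lower by fry, which does not compare it with other genes (adjusted p = 0.00254). ADCY5, a cyclase, fell by 1.06 ± 0.08 and PRKACA, the catalytic subunit, fell by 0.31 ± 0.05, while PRKAR1B rose by 0.30 ± 0.07.

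Genes that respond to cAMP through CREB gave a mixed picture. Of 25 tested, 5 rose, none fell and 20 did not pass (4 rose adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0744). PDE4D and the kinase gene SGK1 (0.46 ± 0.09) were among those that rose. FTO-GFP replicate 2 carried this list at a median of 0.83 log2 units above the mean of replicates 1 and 3. The list passed without FTO-GFP replicate 1 (adjusted p = 0.0136) and without FTO-GFP replicate 3 (0.00910), without FTO-GFP replicate 2 it was at 0.598, and its adjusted p over all alternatives ran from 0.00910 to 0.646.

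MMP3, a matrix metalloproteinase (chromosome 11, 102835801 to 102843803), rose 9.80-fold from 2.34 ± 0.373 CPM in GFP (SD, n = 3; log2 fold change 3.29 ± 0.13, adjusted p = 4.18e-09). ALPP, placental alkaline phosphatase, rose 5.67-fold, although reads may be shared with its close paralogs. The annexin ANXA3 rose 5.43-fold, and the integrin genes ITGB4 and ITGB8 rose 5.18-fold and 4.01-fold. ITGB4 (chromosome 17, 75721328 to 75757818) had the smallest adjusted p among these rises (3.27e-10), at 70.4 ± 0.232 CPM in GFP and 365 ± 27.0 CPM in FTO-GFP. The mucin gene MUC5AC rose 4.61-fold and the nuclear receptor gene NR2F1 4.09-fold. UPK3B, a uroplakin, rose 3.86-fold, the metalloproteinase gene ADAMTS15 3.82-fold and PLCXD3 3.81-fold. Further rises with small adjusted p were CAV1 (caveolin, 3.51-fold), PLAU (urokinase, 2.96-fold), KRT19 (a keratin, 2.92-fold) and TIMP3 (a metalloproteinase inhibitor, 2.86-fold).

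CD70, a ligand of the TNF family (chromosome 19, 6583183 to 6604103), went from 65.2 ± 1.49 CPM in GFP to 3.92 ± 0.165 CPM in FTO-GFP, 16.6-fold lower (log2 fold change -4.05 ± 0.08 SE, adjusted p = 2.09e-11). SLC22A17 was 12.1-fold lower, KIAA1324L 8.85-fold, the noncoding LINC01658 6.79-fold and KCNH2, a potassium channel gene, 6.40-fold. JAKMIP2 was 6.31-fold lower, the receptor tyrosine kinase gene RET 5.71-fold, cytoglobin (CYGB) 5.66-fold, NELL2 5.43-fold and the netrin receptor gene UNC5B 4.98-fold. INAVA was 4.85-fold lower and the plakophilin gene PKP1 4.81-fold. SLC22A17, KIAA1324L and JAKMIP2 were at means of 0.460, 0.895 and 0.833 CPM in FTO-GFP, so their folds rest on few counts. The next falls by adjusted p were MAP2 (a microtubule protein, 3.73-fold), ECM1 (an extracellular matrix protein, 3.01-fold), CYP26A1 (which degrades retinoic acid, 2.93-fold) and APOBEC3G (a cytidine deaminase, 2.91-fold). MMP3, ALPP, NR2F1, ITGB8, PLAU, JAKMIP2, CYGB and CYP26A1 share exons with another annotated gene, and their counts are uncertain to that extent.

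**Figure D2:**
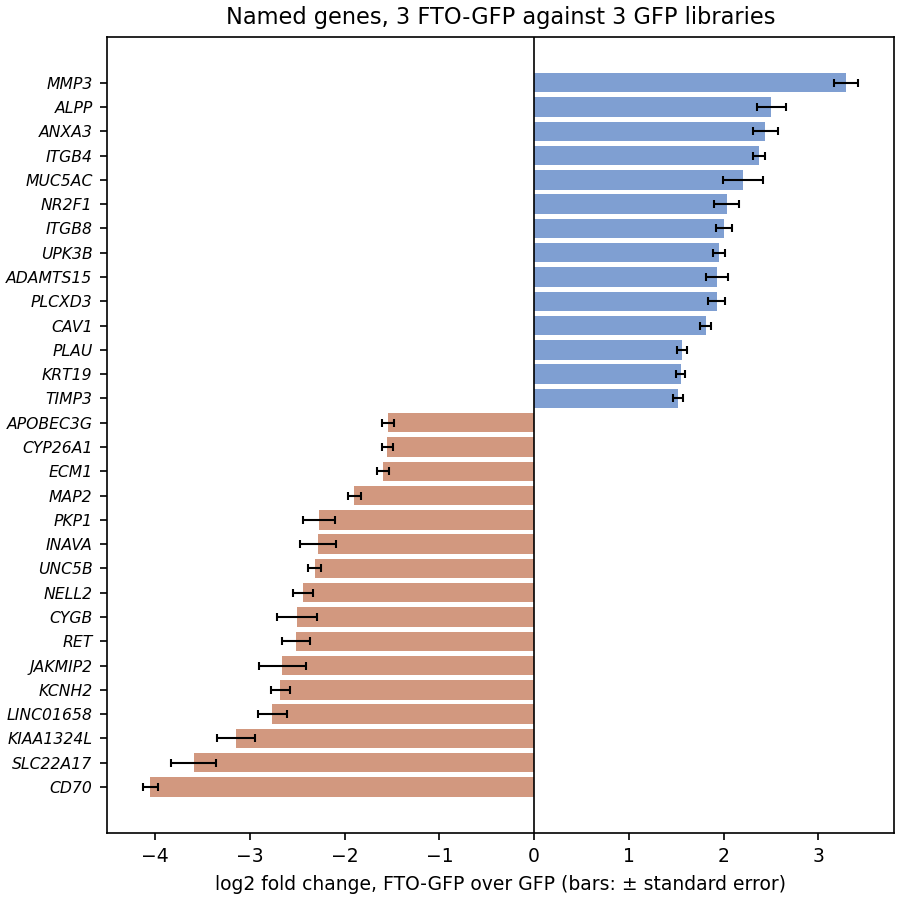
Log2 fold change of FTO-GFP over GFP for the rises and falls named singly, from 3 libraries per group; error bars are standard errors. The values run from -4.05 (CD70) to 3.29 (MMP3).

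Of the 30 gene lists fixed before the data were examined, 15 passed by camera with the preset correlation. Splits of the libraries that mix the groups, with 0 changed genes each, also gave from 5 to 13 lists by this test. Such splits keep part of the difference between the groups, so these counts are not a rate of calls in error. With an estimated correlation only the epithelial list passed. Among lists that lost the call, the estimate was below the preset 0.01 for phosphodiesterases (-0.040), Notch (-0.060), stem cell (-0.034), fibroblast (-0.0081) and immune lists (-0.0030). Correlation among members is not what ended those calls. The other lists that lost it had estimates from 0.013 (TGF-beta) to 0.27 (cholesterol and fatty acid synthesis). For TGF-beta, near the preset, the unadjusted camera p still went from 1.85e-07 to 0.00706 with the estimate. For epithelial genes, with an estimate of -0.019, it went from 1.81e-14 to 0.00105. A higher p with an estimated correlation is therefore not by itself a sign of correlation among members. Epithelial genes were higher: 12 of 24 rose, none fell and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 2.71e-13; adjusted p = 0.0314 with an estimated correlation). The keratin genes KRT19, KRT7 (1.65 ± 0.06) and KRT8 (0.90 ± 0.05) were among those with the smallest adjusted p. Mesenchymal genes were also higher, with 12 of 20 that rose and 3 that fell, the same adjusted over the list alone (camera adjusted p = 0.00525; adjusted p = 0.179 with an estimated correlation). Vimentin (VIM) rose by 0.70 ± 0.05 and fibronectin (FN1) by 0.81 ± 0.06, while COL1A1 fell by 1.15 ± 0.08, TNC fell by 0.34 ± 0.06 and ACTA2 fell by 1.56 ± 0.41 from 0.859 CPM. ACTA2 missed the threshold without GFP replicate 1 (adjusted p = 0.0521) and without GFP replicate 3 (0.0618). COL3A1 rose by 2.23 ± 0.23 from 0.922 CPM.

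Targets of YAP and TEAD, the output of the Hippo pathway, were higher: 16 of 23 rose and ARHGEF17 alone fell, by 0.16 ± 0.05 (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.26e-14; adjusted p = 0.0706 with an estimated correlation). Tissue factor (F3) rose 2.83-fold and the receptor kinase gene AXL 2.18-fold, and on the log2 scale MYOF rose by 1.06 ± 0.06 and AJUBA by 0.90 ± 0.06. The ARHGEF17 call was lost in 8 of 18 alternatives (adjusted p from 0.0538 to 0.158), among them each library left out except FTO-GFP replicate 2. Of 22 TGF-beta targets 10 rose and none fell, also adjusted over the list alone (camera adjusted p = 1.38e-06; adjusted p = 0.0706 with an estimated correlation). These included BMP4 (1.52 ± 0.07), its antagonist NOG (1.61 ± 0.09), THBS1 (1.49 ± 0.09) and TGFB2 (0.91 ± 0.07). Notch targets were lower, with 6 of 12 that fell and 3 that rose (7 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.00788; adjusted p = 0.141 with an estimated correlation). NOTCH3 fell by 1.27 ± 0.08, HEY1 fell by 2.13 ± 0.19, NRARP fell by 0.66 ± 0.09 and DTX1 fell by 1.59 ± 0.23, whereas HES2 (1.27 ± 0.25), LFNG (0.50 ± 0.10) and the ligand gene JAG1 (0.38 ± 0.10) rose. JAG1 missed the threshold without GFP replicate 3 (adjusted p = 0.0651). Of 17 Wnt targets 8 fell and 5 rose (9 and 5 adjusted over the list alone), and the list, with a median of -0.35, did not pass by camera (adjusted p = 0.578) and passed as lower by fry (adjusted p = 0.0272). Cyclin D1 (CCND1) fell by 0.73 ± 0.07 and NKD2 fell by 2.53 ± 0.25, and CD44 (1.58 ± 0.05) and DKK1 (1.43 ± 0.13) rose.

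**Figure D3:**
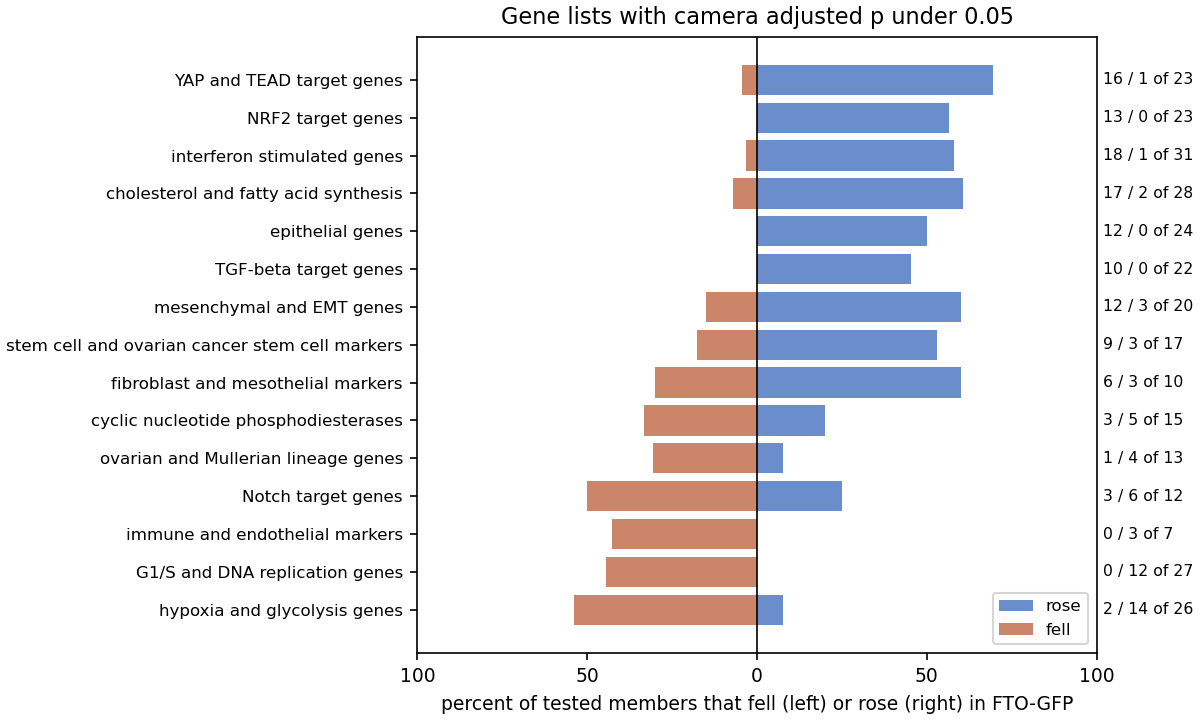
Percent of tested members that rose (right) or fell (left) in FTO-GFP for the 15 gene lists with camera adjusted p under 0.05, with the numbers that rose, fell and were tested at the right edge. YAP and TEAD targets had 16 of 23 members that rose and hypoxia and glycolysis genes 14 of 26 that fell.

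Stem cell markers were higher as a list, with 9 of 17 that rose and 3 that fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.000338; adjusted p = 0.0810 with an estimated correlation). CD44, ALDH1A3 (1.20 ± 0.06) and EPCAM (0.55 ± 0.07) rose, and NOTCH3, FZD7 (fell by 0.25 ± 0.07) and SALL4 (fell by 0.35 ± 0.10) went the other way. The FZD7 call was lost without GFP replicate 1 (adjusted p = 0.0514) and without GFP replicate 3 (0.0921). The SALL4 call was lost without GFP replicate 3 (0.0962), without FTO-GFP replicate 1 (0.0685) and with DESeq2 (0.0865).

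Interferon stimulated genes were higher, with 18 of 31 that rose and BST2 that fell by 1.11 ± 0.10 (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.13e-06; adjusted p = 0.120 with an estimated correlation). IFI44L (1.21 ± 0.09), OASL (1.19 ± 0.09), the RNA sensor DDX58 (1.16 ± 0.09) and IFIT3 (0.66 ± 0.06) had the smallest adjusted p among those that rose. NF-kB and inflammatory genes went both ways, 9 lower and 7 higher of 28 (9 and 8 adjusted over the list alone; camera adjusted p = 0.249). The adhesion gene ICAM1 fell by 0.82 ± 0.05, IL32 fell by 1.11 ± 0.13, CCL2 fell by 0.44 ± 0.07 and TNF fell by 2.85 ± 0.30 from 2.11 CPM, while CXCL8 rose by 0.86 ± 0.14. The median log2 fold change of that list was 0.04 and its mean -0.02, and its median was -0.02 when scaled by library size alone. Without FTO-GFP replicate 2 the list passed as lower (adjusted p = 0.00328, from 0.00328 to 0.683 over all alternatives).

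Genes of hypoxia and glycolysis were lower: 14 of 26 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.000492; adjusted p = 0.250 with an estimated correlation). NDRG1 fell by 1.02 ± 0.07, the enolase gene ENO2 fell by 0.72 ± 0.06, adrenomedullin (ADM) fell by 0.50 ± 0.05 and EGLN3 fell by 0.78 ± 0.09, against rises of the glucose transporter gene SLC2A1 (0.27 ± 0.05) and PFKP (0.25 ± 0.05). Of 28 genes of cholesterol and fatty acid synthesis, 17 rose and 2 fell (18 and 2 adjusted over the list alone; camera adjusted p = 0.000123; adjusted p = 0.351 with an estimated correlation). INSIG1 rose by 0.81 ± 0.08, IDI1 by 0.54 ± 0.06, SC5D by 0.78 ± 0.10 and the transcription factor gene SREBF2 by 0.48 ± 0.07. SQLE, which encodes squalene epoxidase and was the most abundant of the members named, fell by 0.57 ± 0.10, and STARD4 fell by 0.40 ± 0.06. NRF2 targets were higher, 13 of 23 with none lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.000113; adjusted p = 0.195 with an estimated correlation), among them the cystine transporter gene SLC7A11 (1.30 ± 0.09), AKR1C3 (0.78 ± 0.07), HMOX1 (0.63 ± 0.07) and TXNRD1 (0.55 ± 0.05). SLC7A11 also belongs to the list of unfolded protein and ATF4 response genes, where 7 of 24 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.0744, with 0.0395 without FTO-GFP replicate 2, 0.0327 without FTO-GFP replicate 3 and 0.0118 without the genes of shifted chromosome stretches). STC2 rose by 0.87 ± 0.07 and ATF5 by 0.70 ± 0.08, and PHGDH, of serine synthesis, fell by 0.48 ± 0.06. Scaled by library size alone or by upper quartiles, 6 of that list rose and 6 fell.

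DNA replication genes were lower by small amounts: 12 of 27 fell and none rose (13 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00546; adjusted p = 0.416 with an estimated correlation). The helicase subunit gene MCM3 fell by 0.39 ± 0.05 and GINS2 fell by 0.46 ± 0.06. Mitotic genes did not follow them, with 8 of 27 that rose and none that fell (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0965, 0.00832 without FTO-GFP replicate 2, and up to 0.515 over all alternatives). UBE2C rose by 0.36 ± 0.05 and ANLN by 0.39 ± 0.07. Of 24 p53 targets 5 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.468), with CDKN1A, the gene of the p21 inhibitor, lower by 1.17 ± 0.17. Among MAPK feedback and immediate early genes 8 of 25 rose and 8 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.475): DUSP6 fell by 0.69 ± 0.06 and ETV4 fell by 0.72 ± 0.07, and EPHA2 rose by 0.81 ± 0.07. The median of that list was -0.16 and its mean 0.11, and its balance turned with scaling, to 8 rises and 7 falls with RLE and to 6 rises and 10 falls with library size alone.

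Of 24 writers, erasers and readers besides FTO, 1 rose, 5 fell and 18 did not pass, the same adjusted over the list alone (camera adjusted p = 0.468). The reader genes IGF2BP3 and IGF2BP1 fell by 0.28 ± 0.06 and fell by 0.66 ± 0.15, and HNRNPA2B1 fell by 0.19 ± 0.05, a call that was lost without GFP replicate 1 (adjusted p = 0.0576) and without GFP replicate 2 (0.0539). Of 23 transcripts described as FTO substrates in other cancers 8 fell and 5 rose (9 and 6 adjusted over the list alone; camera adjusted p = 0.352). CCND1, ASB2 (fell by 1.24 ± 0.13) and PDCD1 (fell by 2.25 ± 0.24) were lower, and AXL was higher.

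Of 13 ovarian and Mullerian genes 4 fell and PAX8 rose by 0.56 ± 0.10 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00626; adjusted p = 0.321 with an estimated correlation; 0.135 without the genes of shifted chromosome stretches). CRABP2, the most abundant, went from 141 ± 3.94 to 49.1 ± 5.49 CPM (SD, n = 3 each), and FOLR1 fell by 1.35 ± 0.09. Of 12 gastrointestinal lineage genes 4 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.131), among them MUC5AC and MUC2 (1.11 ± 0.23). GATA4, an abundant member, was at 31.9 CPM in GFP and 34.0 CPM in FTO-GFP without passing the test. Fibroblast and mesothelial markers gave 6 rises and 3 falls in 10, also adjusted over the list alone (camera adjusted p = 0.000105; adjusted p = 0.0810 with an estimated correlation). UPK3B and calretinin (CALB2, 23.7 to 74.8 CPM) rose, and C3 (861 to 686 CPM) and COL1A1 (25.8 to 11.7 CPM) fell. Immune and endothelial markers gave 3 falls in 7, also adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.153 with an estimated correlation; 0.0591 without FTO-GFP replicate 2; from 0.000382 to 0.153 over all alternatives), with PECAM1 at 39.4 CPM in GFP and 19.6 CPM in FTO-GFP.

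The lists that speak to RNA quality did not pass by camera with all 6 libraries. By fry, which does not compare a list with other genes, the mitochondrial (adjusted p = 0.0170), histone and noncoding (0.00542) and respiratory chain (0.0228) lists passed. Of 13 mitochondrial mRNAs 5 rose and none fell (7 adjusted over the list alone; camera adjusted p = 0.107, and 0.0458 without FTO-GFP replicate 3), with MT-ND4, the most abundant, at 13709 CPM in GFP and 15363 CPM in FTO-GFP. Of 36 ribosomal protein genes 5 rose and none fell (4 adjusted over the list alone; camera adjusted p = 0.0744), RPL8, the most abundant, being at 2690.1 and 2824 CPM without passing the test. The ribosomal list passed as higher without GFP replicate 3 (adjusted p = 0.0271), without FTO-GFP replicate 1 (0.0272) and without FTO-GFP replicate 3 (0.00811), and was at 0.347 without FTO-GFP replicate 2. RPS25 and RPS6, with the smallest adjusted p, lie in stretches of chromosomes 11 and 9 where neighbouring genes shifted together. Of 12 histone and noncoding RNAs without poly(A) 3 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.224), and HIST1H1C was at 84.1 and 110 CPM. Of 28 respiratory chain genes 3 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.196, and 0.0487 without FTO-GFP replicate 2), and NDUFA4 fell by 0.30 ± 0.05.

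Neighbouring genes shifted together along several chromosomes. On chromosome 11 from 93726654 to 134411918 (GRCh38), 85.6% of 202 tested genes lay above the median fold change of all genes, and their median was 0.44 log2 units above it, a factor of 1.35. The medians were 0.41, 0.38 and 0.42 in FTO-GFP replicates 1, 2 and 3 against the GFP mean. Genes on chromosome 9 from 14521 to 84004074 (212 genes, median 0.28) and on chromosome 14 from 23469688 to 69715142 (236 genes, median 0.25) were also higher. Genes on chromosome 1 from 117953861 to 153361027 (124 genes, median -0.25) and on chromosome 21 from 39405844 to 46665124 (75 genes, median -0.30) were lower. The chromosome 21 stretch shifted less in FTO-GFP replicate 2 (-0.15) than in replicates 1 (-0.34) and 3 (-0.33). In all, 12 stretches, 8 higher and 4 lower, held runs of 50 genes whose median passed 0.23, the value exceeded in 5 of 100 random orders of the genes. They held 707 of the 5336 changed genes that could be placed, and 98 of the 926 changed at least 2-fold. MMP3, ADAMTS15, SC5D and RPS25 on chromosome 11, DDX58 and RPS6 on chromosome 9, BMP4, EGLN3 and ASB2 on chromosome 14, PDE9A on chromosome 21, and PHGDH, ECM1, CRABP2, INAVA and PKP1 on chromosome 1 lie inside them. With the genes of these stretches left out, 4668 genes changed, 839 at least 2-fold, and the phosphodiesterase (adjusted p = 0.0557) and ovarian lists (0.135) no longer passed, while the unfolded protein and ATF4 list did (0.0118).

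**Figure D4:**
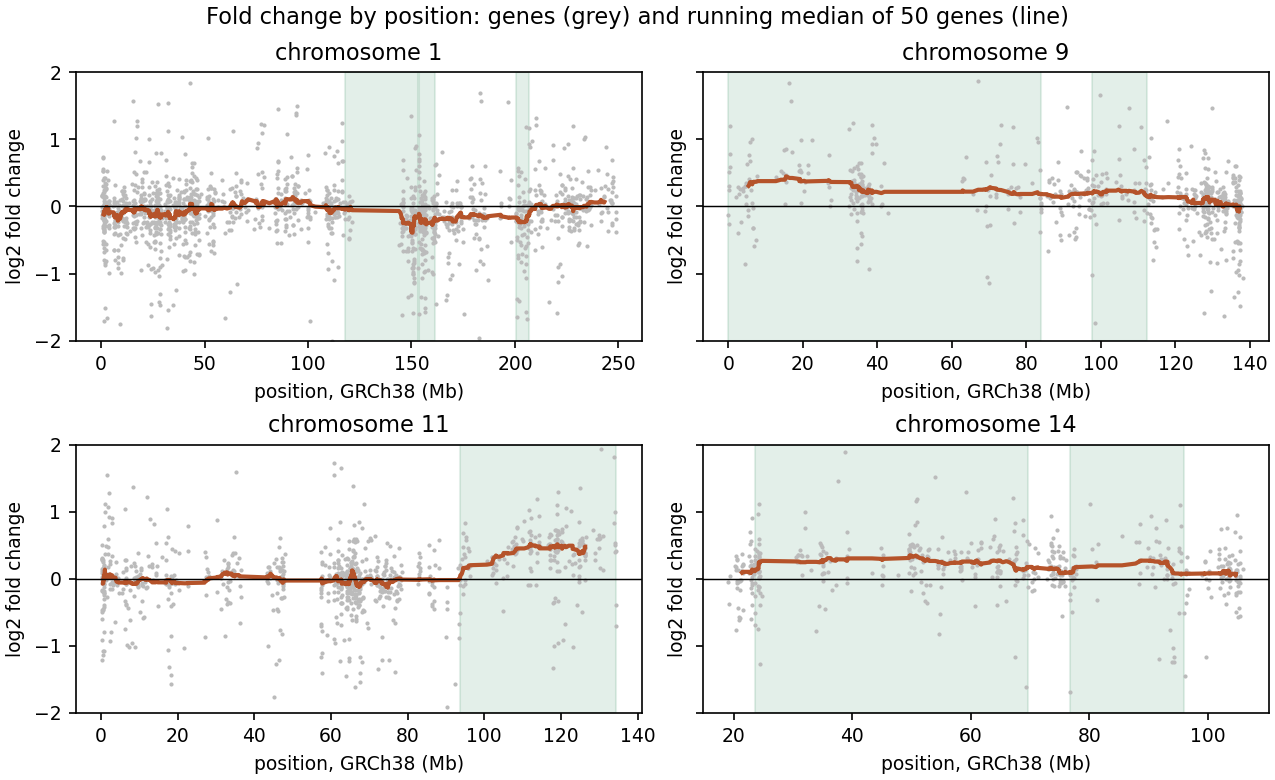
Log2 fold change of FTO-GFP over GFP against gene position on chromosomes 1, 9, 11 and 14 (GRCh38, Mb), relative to the median of all genes; grey points are genes, the line is the running median of 50 genes, green bands are the shifted stretches, and genes beyond the vertical range are not drawn. On chromosome 11 the line leaves 0 near the start of the stretch that begins at 93726654 and stays above it to its last point.

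FTO-GFP replicate 2 stood apart from the other FTO-GFP libraries. The chi-square per degree of freedom of its counts against those of replicates 1 and 3 was 13.2 and 15.5, against 1.76 between replicates 1 and 3 and 1.21 to 2.32 among GFP libraries. Among 12316 genes with a mean of at least 50 counts, 92 differed at least 2-fold from the mean of replicates 1 and 3, 78 of them higher. The list of cAMP and CREB responsive genes had the highest median difference (0.83, above all of 10000 random lists matched on expression), followed by ovarian genes (0.31), MAPK and immediate early genes (0.29) and NF-kB genes (0.28), as a description of this library. Without FTO-GFP replicate 2, 7724 genes changed and 1097 changed at least 2-fold.

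**Figure D5:**
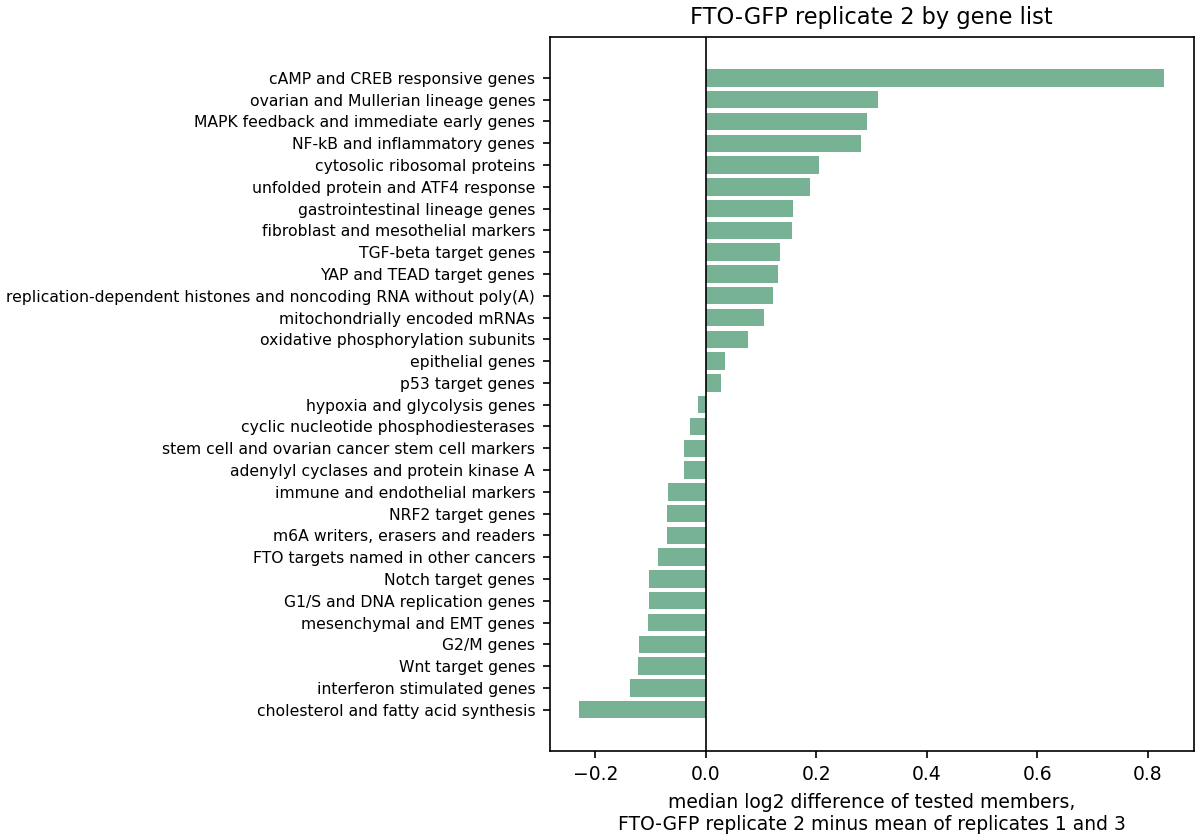
Median log2 difference between FTO-GFP replicate 2 and the mean of FTO-GFP replicates 1 and 3 for the tested members of each of the 30 gene lists, each bar from single libraries without error. The cAMP and CREB responsive genes stand at 0.83 and genes of cholesterol and fatty acid synthesis at -0.23.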

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

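The alternatives that removed trends with GC content and length, and that left out genes of the shifted chromosome stretches, were chosen after the data were seen. The count of changed genes ran from 4341 (DESeq2) to 5837 (GC content and length trends removed) over the alternatives with all 6 libraries, and every gene called in the main test and in an alternative had the same direction in both. It ran from 3841 to 7724 with 1 library left out, from 1912 to 3861 for higher and from 1895 to 3863 for lower genes; the highest of each came without FTO-GFP replicate 2, where 98.4% of the main calls were kept. The count of genes changed at least 2-fold was 450 with only genes of a mean of at least 50 counts, where fewer genes were tested. FTO kept its call in each alternative that tested it, with log2 fold changes from 1.28 to 1.70 with 1 library left out, and PDE1C kept its call throughout. PDE4B kept its direction, between -1.46 and -1.01 with 1 library left out and -1.16 with no filter (adjusted p = 0.0562); its adjusted p over all alternatives ran from 5.94e-30 to 0.0647, and why the call was lost was not tested. The number of lists past the threshold was 1 with a correlation estimated from the data and 26 by fry, which does not compare a list with other genes, and 15 to 19 with 1 library left out. The MAPK list, whose adjusted p ran from 0.236 to 0.993 with 1 library left out, and the Wnt list (from 0.465 to 0.787, and 0.747 where it turned) turned from lower to higher without FTO-GFP replicate 1 and 2 respectively, without passing the threshold; the cause was not tested. Of 179 other named genes, 26 lost their call in at least 1 of 18 alternatives. Changes of sign were found without FTO-GFP replicate 2 for RPL8, at -0.0283 (up to 0.13 with 1 library left out), and for FOSB, at -0.25 (up to 1.61), which that library alone holds at a high level in its group; the cause for RPL8 was not tested. Replicate numbers showed no strong pairing of the libraries: deviations from the group means of same-numbered libraries correlated at -0.00490, 0.0280 and 0.0608. Those of differently numbered libraries correlated at -0.0454 to 0.0181. The highest values (0.0608 and 0.0280) came from same-numbered libraries, so a weak pairing stays open. With a replicate block 5207 genes changed, and 15 lists passed. Smaller changes can be missed: in simulated counts, changes of 0.32 on the log2 scale were recovered at 38.0% and those of 1.5-fold at 72.0%. That simulation did not vary depth, spread or the number of libraries, so it does not say which of them limits the calls.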

Other observations

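The slope and admixture tests on FTO-GFP replicate 2, the test of the shifted stretches against genes changed at least 2-fold, and the test of motif density against the size of the change were chosen after the result was seen. FTO-GFP replicate 2 stood apart in single genes, and those named here were chosen after their values were seen. ATF3 was at 153 CPM in it, at 10.2 and 9.73 CPM in FTO-GFP replicates 1 and 3, and at 7.13, 9.82 and 8.53 CPM in the GFP libraries. NR4A2 was at 62.8 CPM against 8.86 and 9.96 CPM, FOSB at 865 CPM against 142 and 137 CPM, and PPP1R15A, which acts in the stress response of translation, at 421 CPM against 107 and 108 CPM. DDIT4, an inhibitor of mTOR signalling, went the other way, at 40.3 CPM against 90.7 and 97.8 CPM. Of the cAMP and CREB responsive genes, 22 of 25 were higher in replicate 2. None of these 5 genes passed the main test between FTO-GFP and GFP (adjusted p = 0.246 for ATF3, 0.202 for NR4A2, 0.393 for FOSB, 0.198 for PPP1R15A and 0.550 for DDIT4). Without FTO-GFP replicate 2, NR4A2 (log2 fold change 0.75, adjusted p = 1.86e-06), PPP1R15A (0.48, 3.24e-13) and DDIT4 (0.63, 1.34e-16) were higher and FOSB was lower (-0.25, 1.98e-07). These genes were chosen for how that library differed, and leaving it out removes that spread. The p-values without it are therefore no test of an effect of FTO. With robust=FALSE, ATF3 (0.0436), NR4A2 (0.0273) and PPP1R15A (0.0259) passed, and NR4A2 also with DESeq2 (0.0430).

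Of 41 chromosome arms, 23 had an adjusted permutation p under 0.05. Neighbouring genes moved together on 3 arms whose median lay at least 0.15 log2 units from that of all genes: 9p (0.29), 14q (0.17) and 1q (-0.15), each with adjusted permutation p = 0.000373 (unadjusted 0.0001, the smallest that 10000 draws can give). A difference in copy number between the cell populations is a candidate explanation for these shifts, which all FTO-GFP libraries shared; no DNA was measured, and regulation of whole regions was not tested. Differences over such stretches leave most of the larger changes aside, since 10.6% of the genes changed at least 2-fold lay in them, where 8.89% of all placed genes lie. Stretch medians were at most 0.44 in size, too small for a 2-fold change by themselves. Differences shorter than a run of 50 genes were not examined. Among changes of any size, 49.6% of genes in the stretches changed, against 31.7% of other placed genes. A gene inside a stretch may differ for a reason other than FTO. The same holds for genes outside the stretches. The labels do not say whether the libraries of a group came from separately made cell populations, so other differences between populations cannot be told from FTO.

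FTO-GFP replicate 2 had the smallest total and the most FTO mRNA of its group. With all libraries thinned to its total, the chi-square of its pairs was still at least 7.37 times that of replicates 1 and 3, which argues against depth. Across genes selected on another FTO-GFP library and GFP replicate 1, the slope of replicate 2 on the selecting difference was at most 0.950 times (bootstrap SD 0.0139, over genes, which are not independent replicates) that of the remaining FTO-GFP library. This gave no sign of a stronger response to more FTO. Replicates 1 and 3 were much alike, so selection on 1 of them favours the other. A modestly stronger response in replicate 2 could therefore be missed. Of the 92 genes at least 2-fold from the mean of replicates 1 and 3, a share of 0.804 lay 1.5-fold or more beyond all other libraries, which a mixture with GFP cells does not give. A small admixture stays open for the other genes, since the log2 difference from GFP in replicate 2 was a median of 0.805 of that in replicates 1 and 3 among genes that fell at least 2-fold in these, against 0.985 among those that rose, and a difference in handling was not tested.

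Removal of m6A by FTO could change transcripts in proportion to their methylation sites. Across 12869 protein-coding genes, the log2 fold change had a partial Spearman correlation of -0.000679 (bootstrap SD 0.00895) with the density of DRACH motifs in the 3' UTR, given UTR length, UTR GC content and mean expression. With the absolute log2 fold change, for changes in either direction, it was 0.0133 (bootstrap SD 0.00926). These values argue against motif density in the annotated 3' UTR as a main source of the changes, while methylation itself was not measured. With GC content and length trends removed per library, a share of 0.994 of the genes changed at least 2-fold stayed called in the same direction, which argues against those trends as the source of these changes.

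The 10 splits of the 6 libraries are too few for a share under 0.05. Only 1 split, the real one, gave 5414 changed genes, 939 of them at least 2-fold. The highest count of the other splits by edgeR was 0 for both, with 85 to 573 genes at an unadjusted p under 0.05 against 6975. In those splits the difference between the groups adds to the spread within each side, which lowers their counts. The 0 is therefore no measure of how many genes are called in error. The real split gave 15 lists past the threshold, and the others, with 0 changed genes each, gave from 5 to 13. The mixed splits keep part of the difference between FTO-GFP and GFP, so their lists do not measure how often camera calls in error. They show that lists can pass where no single gene does. A list that passes camera at the preset correlation is still weak evidence by itself, since only 1 list passed with an estimated correlation.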
